A study of Sus scrofa with 18 samples.

How the data were processed

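The series holds small RNA and mRNA sequencing of muscle from adult Hechuan black pigs, castrated sows per the labels. Small RNA was sequenced from muscle tissue and from exosomes isolated from the same kind of muscle, in groups called HC-L and HC-P, with 3 libraries in each of the 4 groups. The labels call the HC-P exosomes Y-Exo. The mRNA part holds 3 libraries of HC-L and 3 of HC-P skeletal muscle. Per the labels' protocols, exosomes were obtained from minced and homogenised muscle by differential centrifugation, passage through a fine filter and a commercial isolation kit. Trizol LS was used for exosome RNA and Trizol for tissue RNA. About 1 µg of total RNA went into an Illumina TruSeq Small RNA library, and a service provider did the sequencing, per the labels' protocols. The aligner, the genome build, the miRNA database release, the counting rule and the tests used by the authors are not given in the sources used here. The labels do not say which of HC-L and HC-P is the oxidative muscle, nor whether the replicates are separate pigs. The p-values of the fits therefore measure only the spread between these libraries. Fisher exact tests count miRNAs or genes as independent and measure no spread between libraries.

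The small RNA table of the authors gives a read count per mature miRNA and library, and a deposited TPM value that equals the count divided by the library total times 1e6. It lists 465 mature miRNAs, of which 355 carry a miRBase name and 110 are predicted from the reads and carry the authors' numbers. In 21 of them no library had a read. The 4 deposited tables of changed miRNAs give a group signal, which is a mean of normalised read counts, with a log2 fold change, a p-value and an adjusted p-value by the authors. The mRNA table gives a deposited signal per gene and library. In each library every value was a whole multiple of the smallest one within 0.02 steps, which is the form of read counts divided by a single factor per library. It also gives the log2 fold change, p-value and adjusted p-value of the authors. The table holds 522 genes, with adjusted p-values up to 0.0498 and absolute log2 fold changes from 1.00, so only genes called by the authors are in it. The columns of the mRNA table were assigned to the HC-L and HC-P muscle groups only. Gene symbols came from the deposited description or the reference gene name table, which held 406 of the 522 identifiers. In all, 429 genes had a symbol, and the 2 sources differed for 5 of them.

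The read counts were analysed in R 4.3.3 with edgeR 4.0.16. miRNAs were kept by filterByExpr with the 4 groups as the design, which left 252. Library sizes were scaled by TMM, all 12 libraries entered a single quasi-likelihood fit with a coefficient per group, and the common dispersion was 0.346. Contrasts were exosome against tissue within each muscle, HC-L against HC-P within each kind of sample, and the difference of the exosome-tissue differences. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and an adjusted p under 0.05 was called a change. Values in counts per 1e6 counts (CPM) are scaled by TMM unless library totals are named, and errors of log2 fold changes are standard errors from the fit. Where a group had no read in any library, the fold was computed against a floor of 3 counts over the group. Ratios of pooled reads use library totals scaled by TMM and carry exact 95% binomial intervals. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. For the mRNA table no test of change was run, because it holds only called genes, and the calls of the authors were counted. With an mRNA library left out, the called genes that kept their direction and an absolute log2 ratio of the remaining group means of at least 1 were counted, by a rule set after the data had been seen.

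The small RNA libraries of tissue held between 3964875 and 9016010 miRNA reads, and those of exosomes between 106040 and 959599. A floor of 3 reads is 0.333 to 0.757 CPM of the library total in tissue and 3.13 to 28.3 CPM in exosomes. Counts of 252 miRNAs were simulated with the real library sizes and with means from the tissue libraries alone, for exosomes as well. miRNAs that failed the filter in a run could not be called and are left out of the shares below. The fit called 7.46% of the miRNAs given a log2 change of 1 between exosomes and tissue and 40.2% of those given 2, in either muscle. At a log2 change of 4 it called 80.3% in HC-L and 88.7% in HC-P. Of the unchanged miRNAs it called 0.431% in either muscle.

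The following choices were made before the data were examined: the groups, the fit, the thresholds, the lists, the rule for named genes and the alternatives, apart from those said below to be added. For each contrast the rule named the 10 miRNAs with the largest change in each direction among those called, with no overlap between the groups and with a mean of at least 50 CPM in either group. It also named the 10 miRNAs with the highest share in each group, all forms of miR-4331 and the most abundant members of each list. For mRNA it named the 10 genes with a symbol and the largest change in each direction among those with a group mean at or above the median of 219, and up to 6 members per list. There were 17 miRNA lists: muscle-enriched (myomiR), slow-fibre myosin-intron, erythroid, myeloid and lymphoid, endothelial, smooth muscle, fibroblast and mesenchymal, epithelial, liver and plasma, neural, the let-7 family, miR-17-92 and paralogues, miR-23-27-24 clusters, the miR-29 family, the miR-30 family, the miR-10-99-100-125 group and the DLK1-DIO3 imprinted cluster. The 17 mRNA lists were slow fibre, fast fibre, glycolysis and glycogen, TCA cycle, oxidative phosphorylation, fatty acid oxidation and uptake, mitochondrial biogenesis and oxidative regulators, myogenic regulators, positional homeobox and T-box, adipocyte, extracellular matrix and fibroblast, endothelial, immune, erythroid, nerve and Schwann, immediate early and heat shock, and exosome biogenesis and sorting. The miRNA lists with at least 3 tested members were tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 on log2 CPM with a prior count of 2, and with an estimated correlation and fry beside it. mRNA lists with at least 3 genes in the table were tested for direction by a two-sided Fisher exact test against the other genes of the table, which counts genes as independent.

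The alternatives were DESeq2 size factors in the same fit, library totals alone, totals without the 3 most abundant miRNAs, the Wald test of DESeq2 1.42.0, no filter on low counts, a filter of at least 10 CPM in 3 libraries, an absolute log2 fold change of at least 1, a fit of only the 2 groups compared, a replicate block, and each library left out in turn. Thinning every library to 106040 reads, leaving out the 3 shallowest exosome libraries, taking miRNAs with equal counts once in the list tests and the comparison of miRNA arms were added after the data had been seen. For the arms, reads were thinned to 106040 per library, hairpins with a mean of at least 3 reads for each arm were kept, and 0.5 reads were added to each arm before the log2 ratio. Exosome and tissue libraries were exchanged within each muscle in all 400 ways, which gives a smallest p of 0.005. Tested on 20 simulated data sets with a library spread of 0.5 on the log2 scale, this called 87.5% of hairpins given a 4-fold shift and 1.67% of those given none. The real ratios of many hairpins spread more, with an SD up to 1.87 in tissue and 1.27 in exosomes. The share of 87.5% therefore may not hold for these data.

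Whether equal replicate numbers pair the libraries was checked on deviations from group means. The correlations of same-numbered libraries were 0.39, 0.37 and 0.53 between HC-L exosomes and HC-L tissue, 0.34, 0.21 and 0.30 between the exosome groups, and 0.17, 0.13 and 0.23 between the tissue groups. For HC-P exosomes and HC-P tissue they were 0.11, 0.04 and 0.14, and there exosome replicate 2 correlated best with tissue replicate 1. In the other 3 contrasts each library of the first group correlated best with the equal number of the second. No contrast was tested alone for pairing, and the labels give none. Figures and permutation tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.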

Results

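Small RNA was counted in muscle tissue and in muscle-derived exosomes of Hechuan black pigs, in the muscle groups HC-L and HC-P, to compare the miRNA content of exosomes with that of their tissue and between an oxidative and a glycolytic muscle. Each of the 4 groups had 3 libraries. HC-L tissue libraries held 7331196, 9016010 and 6944879 miRNA reads and HC-P tissue libraries 3964875, 6507823 and 6690912. HC-L exosome libraries held 674732, 631193 and 275361 reads and HC-P exosome libraries 959599, 168341 and 106040. mRNA values of 3 HC-L and 3 HC-P muscle libraries were given for the genes called by the authors.

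The muscle miRNA miR-1 was the most abundant in every group. It took 65.3% ± 6.62 (SD, n = 3) of miRNA reads in HC-L tissue, 55.2% ± 24.3 in HC-P tissue, 45.2% ± 15.1 in HC-L exosomes and 42.4% ± 6.27 in HC-P exosomes. miR-206, another muscle miRNA, took 8.57% ± 4.28 and 6.79% ± 0.496 of tissue reads and 15.4% ± 6.34 and 17.8% ± 2.04 of exosome reads, in HC-L and HC-P. miR-26a took 3.38% ± 0.93 and 3.28% ± 0.639 in tissue and 8.11% ± 0.327 and 8.02% ± 1.16 in exosomes. As a share of the library total it was higher in every exosome library than in every tissue library, while its TMM-scaled values overlapped. miR-148a-3p reached 4.95% ± 0.843 of reads in HC-L exosomes and 4.61% ± 1.56 in HC-P exosomes, against 1.85% ± 0.849 in HC-L tissue. The other miRNAs among the 10 most abundant of at least 1 group were miR-143-3p, miR-21-5p, miR-133a-3p, miR-378, miR-10b, miR-30d, miR-7134-3p, miR-126-3p, let-7f-5p, let-7i-5p and miR-128. HC-P tissue replicate 1 stood apart from the other tissue libraries. Its miR-1 share was 27.4%, while miR-133a-3p took 13.3%, miR-30d 10.7% and miR-378 8.02% of its reads, against at most 2.28%, 1.41% and 2.71% in the other 5 tissue libraries.

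A small set of miRNAs had far higher CPM in exosome libraries than in tissue libraries of both muscles. Whether this reflects the content of vesicles or a similar number of reads entering every exosome library stays open, as weighed further below. In HC-L, miR-10386 reached 597 ± 687 CPM in exosomes against 1.03 ± 0.181 in tissue (SD, n = 3; log2 fold change 9.12 ± 1.36, edgeR adjusted p = 0.000757), and miR-1285 reached 592 ± 298 against 16.9 ± 3.37 (5.13 ± 0.80, adjusted p = 0.000757). In HC-P, miR-10386 was at 483 ± 90.4 against 8.61 ± 12.4 CPM (5.78 ± 1.15, adjusted p = 0.00479) and miR-1285 at 767 ± 656 against 19.1 ± 7.46 (5.32 ± 0.81, adjusted p = 0.000738). The predicted miRNA novel_453 had 112 reads in HC-L exosomes and none in HC-L tissue, at least 289-fold higher, and was at least 88.2-fold higher in HC-P exosomes. novel_295 had 147 reads in HC-P exosomes and none in HC-P tissue, but all except 6 of them were in replicate 1, and the bound fell from at least 463-fold to at least 64.5-fold without that library. novel_509 was 364-fold higher in HC-P exosomes by pooled reads (95% interval 97.3 to 3060), and 710-fold without replicate 1. Without HC-P tissue replicate 1 the miR-10386 value in HC-P was 8.43, and without HC-L exosome replicate 3 that in HC-L was 8.03. Without HC-P exosome replicate 3 the miR-1285 value in HC-P was 4.58. Among the abundant miRNAs, let-7i-5p was higher in exosomes of both muscles, with log2 fold changes of 1.41 ± 0.42 in HC-L (adjusted p = 0.0376) and 1.75 in HC-P (adjusted p = 0.012). In HC-L it lost its call in 5 of the 12 fits with a library left out, and its value was 2.03 without HC-L tissue replicate 3.

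miR-30e-5p and miR-101 were the miRNAs lower in exosomes of both muscles under all 5 combinations of scaling and tool. miR-30e-5p changed by -3.14 ± 0.50 in HC-L (906 ± 15.7 against 7990 ± 416 CPM, adjusted p = 0.000757) and by -2.69 ± 0.49 in HC-P (1400 ± 204 against 9030 ± 5410 CPM, adjusted p = 0.00214). miR-101 changed by -3.07 ± 0.61 in HC-L (adjusted p = 0.00578, and up to 0.0544 with a library left out) and by -2.78 in HC-P (adjusted p = 0.00643), where the 5 combinations gave -2.78 to -1.64. In HC-P, miR-7134-5p changed by -4.08 ± 0.83 and miR-450c-5p by -3.23 ± 0.67, and both stayed called under these 5 combinations, as did miR-424-5p in HC-L at -5.63 to -4.78, a miRNA named after its values were seen. The other named miRNAs called lower in HC-L were miR-208b, miR-340, miR-19b, miR-450c-5p, miR-218-5p, miR-30a-5p, miR-143-3p and miR-30b-5p, with log2 fold changes from -2.60 to -2.06. Each of these 8, and miR-222 among the higher ones, lost its call with library totals alone, and all of these but miR-30a-5p also in 4 to 10 of the 12 fits with a library left out. Then miR-208b went to -1.75 without HC-L tissue replicate 3, miR-340 to -1.80 without HC-L tissue replicate 2 and to -1.82 without HC-L exosome replicate 3, and miR-218-5p to -1.61 without HC-L tissue replicate 2. In HC-P they were miR-574-3p (-4.91 ± 1.18), miR-1306-5p, miR-214-3p, miR-365-3p, miR-320, miR-133a-3p and miR-425-3p, and the last 6 of these lost their call with library totals. Without HC-P tissue replicate 1, miR-1306-5p went from -3.77 to -1.77, miR-214-3p from -3.10 to -1.22 and miR-320 from -2.61 to -0.66, and none of these 3 was then called. The same omission took miR-574-3p to -1.95, miR-7134-5p to -2.20, miR-365-3p to -1.90 and miR-133a-3p to -1.32, which kept their call (adjusted p = 0.0175, 0.0119, 0.00895 and 0.0125). Without HC-P tissue replicate 3, miR-450c-5p was at -2.14 and miR-30e-5p at -1.98 in HC-P, and both stayed called. The remaining named miRNAs called higher were miR-222 and miR-1468 in HC-L and miR-4331-3p, miR-10390, miR-200b, miR-182, miR-223 and miR-221-3p in HC-P. With the replicate block miR-1468 was not called (adjusted p = 0.0534). Without HC-P exosome replicate 2, miR-10390 went from 5.14 to 2.51 and lost its call (adjusted p = 0.0888), as did miR-223 (adjusted p = 0.0554), and without HC-P exosome replicate 3 miR-221-3p went from 3.00 to 2.32 and lost its call (adjusted p = 0.06).

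By edgeR, 41 of the 252 miRNAs tested differed between HC-L exosomes and tissue, 16 higher and 25 lower in exosomes, and 65 differed in HC-P, 23 higher and 42 lower. Both muscles shared 14 of the higher miRNAs, against 1.46 for independent lists (Fisher exact p = 2.76e-15), and 16 of the lower ones, against 4.17 (Fisher exact p = 1.61e-08), and 0 went in opposite directions. These tests count miRNAs, and the errors of both contrasts, as independent. Yet both contrasts came from the same fit, and same-numbered libraries of the muscles deviated together. With a library left out, the HC-L count ran from 10 to 81 and the HC-P count from 31 to 83, the highest of each without HC-P tissue replicate 1. DESeq2 called 46 in HC-L (27 higher, 19 lower) and 65 in HC-P (35 higher, 30 lower). The authors' tables gave 88 miRNAs with an adjusted p under 0.05 in HC-L (52 higher, 36 lower) and 34 in HC-P (26 higher, 8 lower), which include 39 of the 41 and 29 of the 65 called here, in the same direction. The log2 fold changes of the muscles, which share no library, correlated across miRNAs with Pearson r = 0.827 and Spearman rho = 0.738, where miRNAs are not independent replicates. The split between higher and lower moved with the scaling: higher miRNAs made up 39.0% of the HC-L calls with TMM, 68.0% with DESeq2 size factors, 86.4% with library totals and 80.8% with totals without the 3 most abundant miRNAs, and 35.4%, 56.9%, 86.1% and 79.6% in HC-P. The median log2 fold change of all miRNAs in HC-L moved from -0.40 with TMM to 0.72 with library totals, and in HC-P from -0.70 to 0. Under all 5 combinations of scaling and tool, 15 miRNAs were called higher and 3 lower in HC-L, and 21 higher and 4 lower in HC-P. Of these, 12 higher ones were common to both muscles: novel_295, novel_453, novel_470, novel_509, let-7i-5p, miR-10386, miR-10390, miR-1285, miR-182, miR-200b, miR-4331-3p and miR-4332. Those of the 12 outside the naming rule were named after their values were seen.

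Of the epithelial miRNAs, miR-200b and miR-182 were called higher in exosomes of both muscles. In HC-P, 4 of the 5 tested members were called higher and 5 when adjusted over the list alone, with miR-200b at 65.9 ± 46.9 against 1.97 ± 0.489 CPM (4.97 ± 0.90), miR-182 at 52.1 ± 30.3 against 3.94 ± 0.783 (3.67 ± 0.67), miR-205 at 4.90 and miR-96-5p at 4.23. Without HC-P exosome replicate 2, miR-182 in HC-P was at 3.04 and stayed called. In HC-L, 2 of 5 were called, miR-200b (3.39) and miR-182 (2.08), and 3 when adjusted over the list alone. The list median was 2.08 in HC-L (camera adjusted p = 0.00154) and 4.23 in HC-P (camera adjusted p = 6.96e-06), and the adjusted p with an estimated correlation was 0.366 and 0.0997. The list's other entries were not among the tested miRNAs. Members low in tissue pass the count filter through their exosome libraries. Selection by that filter can therefore favour positive values here, and these counts and camera p-values do not allow for it. All 10 tested let-7 family members had positive values in HC-L (median 0.86, camera adjusted p = 0.0456, up to 0.217 with a library left out, and adjusted p = 0.551 with an estimated correlation) and 8 of 10 in HC-P (median 0.63, adjusted p = 0.0998), with let-7i-5p as the member called in both. The HC-L list lost its call in 8 of the 12 fits with a library left out. No list passed the threshold of 0.05 in any of the 4 contrasts with an estimated correlation.

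Muscle-enriched miRNAs had negative list medians under every scaling run, with -1.42 in HC-L and -1.49 in HC-P by TMM. The list did not pass camera (adjusted p = 0.21 and 0.412), and the medians of all tested miRNAs were -0.4 and -0.7. Of 7 members, miR-208b was called lower in HC-L, and miR-133a-3p, miR-486 and miR-208b in HC-P, while 4 and 5 members passed when adjusted over the list alone. miR-1 had -1.42 and -1.46 (adjusted p = 0.169 and 0.114) and miR-206 had -0.23 and 0.53. HC-P tissue replicate 1 held 1.45% miR-486 and 13.3% miR-133a-3p. Both slow-fibre myosin-intron miRNAs, miR-208b (-2.60 and -2.14) and miR-499-5p (-1.67 and -1.49), passed in both muscles when adjusted over the list alone. Of 3 members of the miR-29 family, 0 were called in HC-L and 2 in HC-P (medians -1.45 and -1.76), and 3 passed in each over the list alone. The miR-29 list did not pass camera (adjusted p = 0.2 and 0.307). In the miR-30 family of 10, 3 members were lower in HC-L (miR-30e-5p, miR-30a-5p and miR-30b-5p) and 4 in HC-P, where miR-30a-3p (1.76) and miR-30e-3p (1.82) were higher. Adjusted over the list alone, 2 members were higher in each muscle, and 4 were lower in HC-L and 5 in HC-P. The family's median was -0.82 in HC-L, turning to 0.25 with library totals, and -1.49 in HC-P, and the list did not pass camera (adjusted p = 0.319 and 0.361).

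Endothelial miR-222 was called higher in both muscles (2.62 and 2.46) and miR-221-3p in HC-P (3.00), while miR-126-3p had -0.06 and -0.04. Without HC-L tissue replicate 3, miR-222 in HC-L went to 3.45 and lost its call (edgeR adjusted p = 0.0649). In the myeloid and lymphoid list of 8, 0 members were called in HC-L (median 1.26) and 1 in HC-P, the neutrophil miRNA miR-223 (median 0.99). For the fibroblast and mesenchymal list of 7, the medians were -1.47 and -0.95, with miR-21-5p called lower in HC-L and miR-214-3p in HC-P, and the HC-P median turned to 0.15 with library totals. The erythroid list had medians of -0.37 and -0.80, with miR-16 lower in both muscles, miR-15a lower in HC-L (-2.28, adjusted p = 0.0432), miR-486 lower and miR-363 higher in HC-P (2.08, adjusted p = 0.0336), and miR-451 at -0.21 and 0.15. In the smooth muscle list (-0.46 and -0.81) miR-143-3p was lower in both, and in the miR-23-27-24 clusters (-0.64 and -0.12) miR-27b-3p and miR-24-3p were lower in both. The liver and plasma list (-1.16 and -1.48) and the DLK1-DIO3 imprinted cluster (-0.69 and -0.46) had 0 calls in either muscle. Neural miR-7-3p and miR-19b of the miR-17-92 list were lower in HC-L, with list medians of 0.26 and 0.69, and -0.91 and -0.37. miR-125b was lower in HC-P, in the list of miR-10, miR-99, miR-100, miR-125a and miR-125b forms with medians of -0.21 and -0.68. Adjusted over the list alone, counts differed for fibroblast and mesenchymal (3 lower in HC-L), smooth muscle (2 lower in HC-P), endothelial (2 higher and 1 lower in HC-P), neural (2 higher in HC-P, miR-9 and miR-9-1, which carry equal counts and do not pass when taken once, adjusted p = 0.0697) and the miR-10 list (0 in HC-P). Under at least 1 other scaling the medians of the smooth muscle, miR-17-92, miR-23-27-24 and DLK1-DIO3 lists turned positive in both muscles, and those of the erythroid list and the miR-10 list in HC-L. None of the lists in this paragraph passed camera in either muscle.

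**Figure D1:**
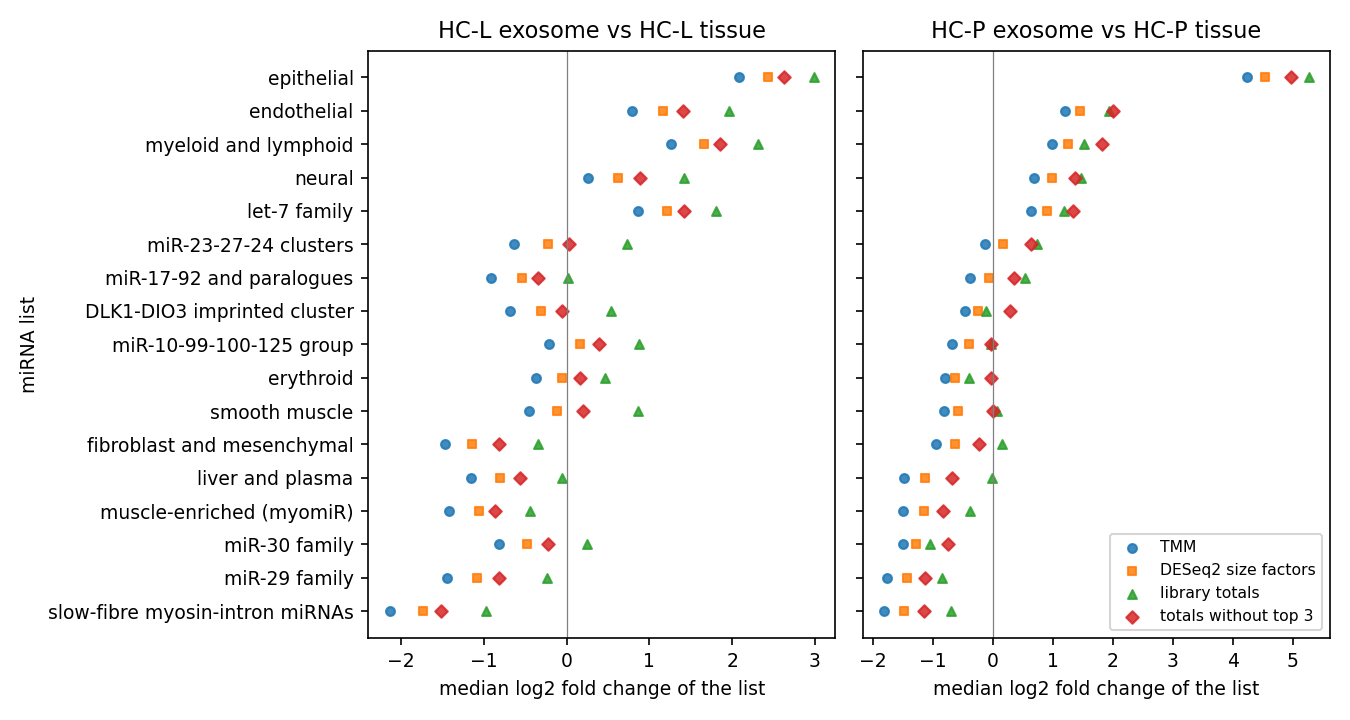
Median log2 fold change of exosomes over tissue for each miRNA list (horizontal axis) in HC-L and HC-P, with a marker per scaling. The epithelial list lay between 2.08 and 2.99 in HC-L and between 4.23 and 5.26 in HC-P, and the muscle-enriched, slow-fibre and miR-29 lists lay below 0 under every scaling. The miR-30 median lay at 0.25 in HC-L and the fibroblast and mesenchymal median at 0.15 in HC-P with library totals, against -0.82 and -0.95 with TMM.

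The arms of the same hairpin parted between exosomes and tissue, a comparison that needs no scaling between libraries and that was chosen after the miR-30 values were seen. All exosome libraries differed from all tissue libraries in isolation and RNA reagent as well. An effect of these on the arms cannot be told apart from a difference in miRNA content. For miR-30e the log2 ratio of 3p to 5p reads was -3.48 ± 0.71 in tissue and 0.71 ± 0.96 in exosomes (SD, n = 6 each), with differences of 4.31 in HC-L and 4.08 in HC-P. For miR-30a it was -5.75 ± 0.38 in tissue and -1.85 ± 1.09 in exosomes. The 3p arm also gained in exosomes for miR-148a (8.37 to 11.57), miR-126 (5.30 to 7.23), miR-151, miR-7134 and miR-199a, while the 5p arm gained for miR-22 (6.10 to 3.26), miR-425 (-2.25 to -4.52), miR-143 and miR-133a. The minor arms of miR-148a, miR-425 and miR-143 had only 63, 59 and 48 reads over all exosome libraries before thinning. The sizes for these hairpins therefore depend on the 0.5 reads added to each arm. With 2 reads added, 11 hairpins passed as well. In all, 11 of 19 hairpins passed the exact permutation test within muscles, each with p = 0.005, the smallest the design can give (adjusted p = 0.00864). The arms of miR-30a and miR-30e have similar sequences, and how shared reads were counted is not given in the sources used here. miR-199a-3p and miR-199b-3p carry equal counts, so the 3p reads given for miR-199a may come from either hairpin.

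**Figure D2:**
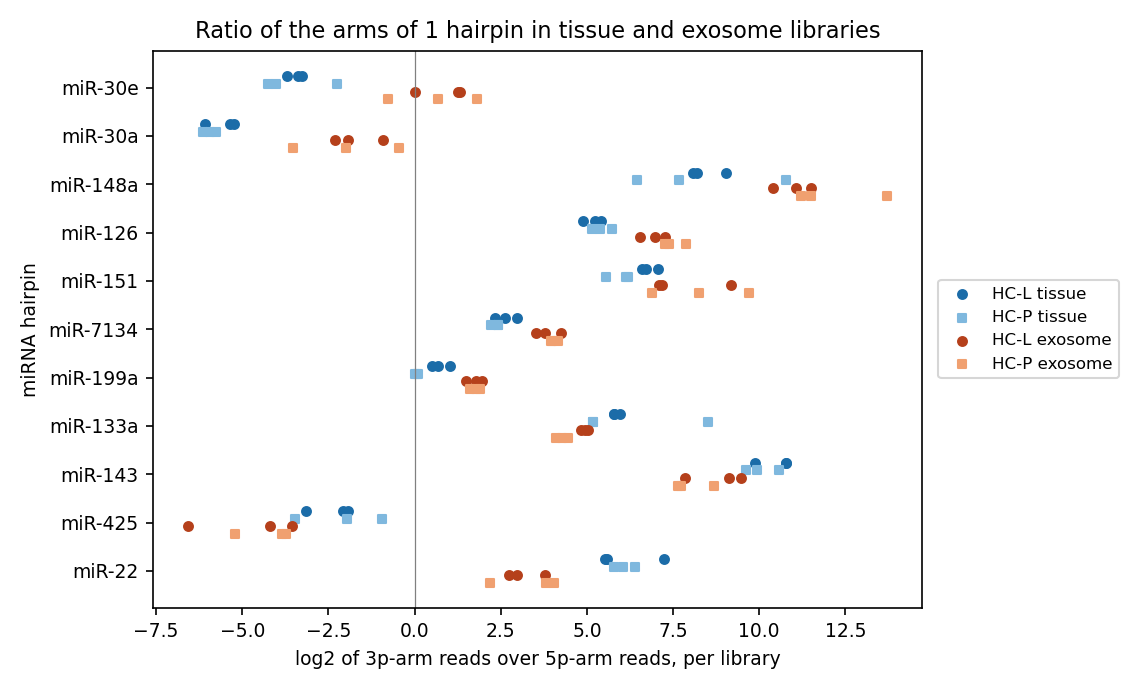
Log2 ratio of 3p to 5p reads of the 11 hairpins with an adjusted p under 0.05, with a point per library, after thinning to equal totals. miR-30e lay at -3.48 on average in the 6 tissue libraries and at 0.71 in the 6 exosome libraries.

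miR-4331-3p, the miRNA in the study's title, was higher in exosomes than in tissue of both muscles, at low read numbers. Tissue libraries held 4, 3 and 3 reads in HC-L and 2, 1 and 1 in HC-P, and exosome libraries 27, 30 and 26 in HC-L and 84, 51 and 53 in HC-P. The level was 44.7 ± 6.69 CPM in HC-L exosomes against 0.685 ± 0.0539 in HC-L tissue (log2 fold change 5.93 ± 0.66, edgeR adjusted p = 7.81e-05) and 180 ± 90.1 in HC-P exosomes against 0.271 ± 0.0514 in HC-P tissue (9.13 ± 0.76, adjusted p = 2.11e-06; SD, n = 3). Pooled reads over TMM-scaled totals gave a 64.2-fold difference in HC-L (95% interval 33.2 to 139) and a 444-fold difference in HC-P (171 to 1650). Over the 5 combinations of scaling and tool the log2 fold change ran from 5.93 to 7.0 in HC-L and from 9.13 to 10.02 in HC-P. Over all 21 alternatives it ran from 5.81 to 7.0 in HC-L and from 8.08 to 10.02 in HC-P. The other arm, miR-4331-5p, had values of -0.26 ± 1.45 in HC-L and 0.00 ± 1.34 in HC-P. As a share of the library total, miR-4331-3p was at 40.0, 47.5 and 94.4 CPM in HC-L exosomes and at 87.5, 303 and 500 CPM in HC-P exosomes, where the values of 303 and 500 came from the libraries with 168341 and 106040 reads.

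**Figure D3:**
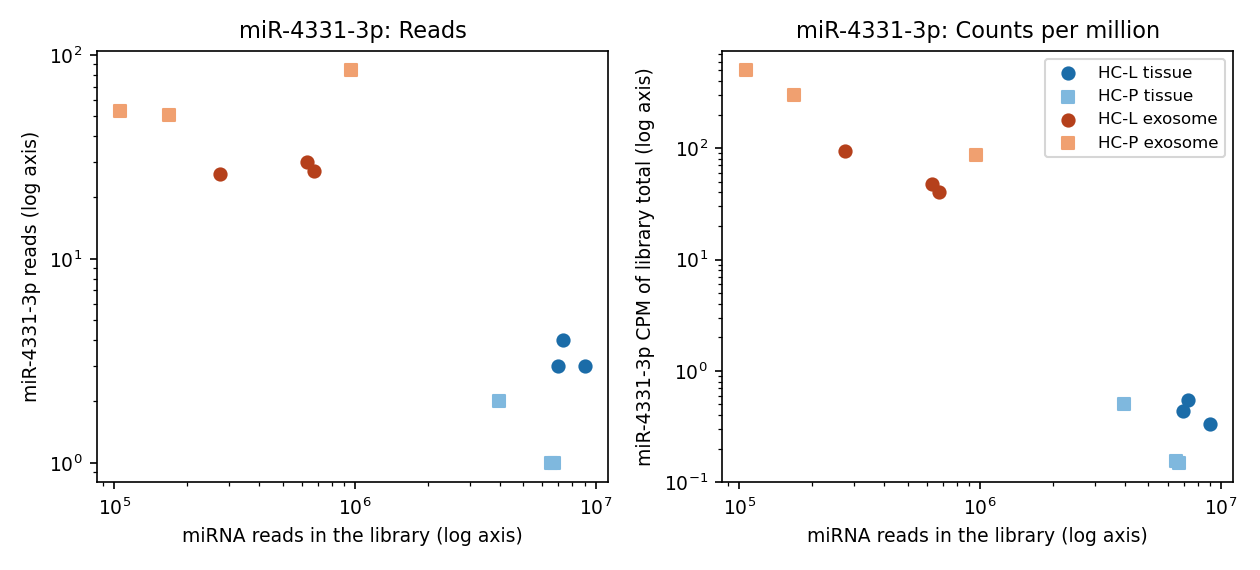
Reads of miR-4331-3p (left) and its CPM of the library total (right) against the miRNA reads of each library, on log axes, with a point per library. HC-P exosome libraries held 51 to 84 reads and HC-L exosome libraries 26 to 30, while tissue libraries held 1 to 4.

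Between the exosomes of the muscles, miR-4331-3p and novel_509 had higher values in HC-P, and neither was called by edgeR. miR-4331-3p had a log2 difference of -2.0 ± 0.54 for HC-L over HC-P (edgeR adjusted p = 0.289), and novel_509, named after its values were seen, was at 4.35 against 75.2 CPM (-4.0 ± 0.95, adjusted p = 0.289). edgeR called 0 of 252 miRNAs, with 8 at an unadjusted p under 0.05, while DESeq2 called both of these, miR-4331-3p at -2.10 (adjusted p = 0.0304) and novel_509 at -4.13 (adjusted p = 0.00174). Over 21 alternatives the adjusted p of miR-4331-3p ran from 0.0304 to 1, and without the 3 shallowest exosome libraries, which leaves HC-P with replicate 1 alone against 2 HC-L libraries, its value was -0.91 (edgeR adjusted p = 1). The authors' table gave miR-4331-3p -2.07 (adjusted p = 0.0672) and novel_509 -4.07 (adjusted p = 0.00201), the latter being the single one of its 6 miRNAs with an adjusted p under 0.05. No list passed between the exosome groups: the list medians ran from -0.55 for myeloid and lymphoid to 0.58 for fibroblast and mesenchymal, and 0 list members were called.

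Between the tissues of the muscles, the fibroblast and mesenchymal list had a median of 0.93 for HC-L over HC-P, with 6 of 7 members positive and 0 called (camera adjusted p = 0.00811, and adjusted p = 0.837 with an estimated correlation). The camera adjusted p was 0.0513 without HC-P tissue replicate 2 and 0.0794 without replicate 3. Among them miR-21-5p was at 0.83, miR-199a-3p at 1.02 and miR-214-3p at -1.21, and miR-199a-3p and miR-199b-3p carry equal counts, with a camera adjusted p of 0.0491 for the list when they are taken once. No single miRNA was called: edgeR gave 0 of 252, with 28 at an unadjusted p under 0.05, and DESeq2 gave 0. miR-4331-3p had 1.20 ± 0.68 (adjusted p = 0.555). Without a filter on low counts, 28 miRNAs were called lower in HC-L. The median of all miRNAs moved from 0.01 with TMM to -0.47 with library totals. The authors' table listed 14 miRNAs, 0 of them with an adjusted p under 0.05. The other lists had medians between -0.28 (miR-30 family) and 0.83 (DLK1-DIO3 cluster) and did not pass.

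The exosome-tissue difference itself did not differ between the muscles for any miRNA after adjustment. edgeR called 0 of 252, with 8 at an unadjusted p under 0.05, and DESeq2 called 0. miR-4331-3p had the value -3.19 ± 0.88 (edgeR adjusted p = 0.712). Without a filter, 5 miRNAs were called, which were let-7d-3p, miR-10386, miR-423-5p, miR-574-3p and miR-6782-3p, named after their values were seen. HC-P tissue replicate 1, which stood apart, may stand behind some of these calls. It held 0.819% miR-423-5p, against at most 0.0226% in the other 5 tissue libraries. Without it the filtered fit in HC-P took miR-574-3p from -4.91 to -1.95 and miR-10386 from 5.78 to 8.43. The fit without a filter was not rerun without that library.

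In muscle mRNA the authors called 522 genes, 356 higher in HC-L and 166 higher in HC-P, and the values below are theirs. Among the genes highest in HC-L, the cardiac and stress-responsive ankyrin repeat gene ANKRD1 was at 58075 ± 16777 normalised reads against 1038 ± 911 (SD, n = 3; log2 fold change 5.81, adjusted p = 7.65e-08). The zinc finger gene ZIC1 was at 293 ± 88.0 against 1.36 ± 1.64 (7.85, adjusted p = 2.86e-19) and the actin regulator ENAH at 15608 ± 4834 against 863 ± 268 (4.18, adjusted p = 8.73e-32). ARC, NTSR2, CSRP3, C11orf52, RTKN2, FOS and ADAMTS4 were also higher in HC-L, with log2 fold changes from 4.15 to 6.52. In HC-P the T-box gene TBX1 was at 3047 ± 515 against 229 ± 62.1 (-3.73, adjusted p = 6.96e-37), the lipid droplet gene PLIN5 at 1358 ± 90.1 against 178 ± 196 (-2.93, adjusted p = 0.000171) and the glycogen phosphatase subunit PPP1R3B at 6522 ± 1542 against 1266 ± 864 (-2.37, adjusted p = 0.000795). MYLK4, MN1, PITX3, ABHD4, TRNP1 and the fructose transporter SLC2A5 were also higher in HC-P, from -3.10 to -1.91.

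Of the 22 genes listed for fatty acid oxidation and uptake, 4 were in the table of called genes, and these were higher in HC-P: LPL (-1.28, adjusted p = 0.00639), ACSL1 (-1.06), CPT2 (-1.26) and MLYCD (-1.66) (Fisher exact p = 0.00998, adjusted 0.0282). Of 15 adipocyte genes 8 were in the table, all higher in HC-L, among them SCD (1390 ± 345 against 237 ± 14.4, log2 fold change 2.55), FASN (1.43), CIDEC (1.81), PLIN1 (2.05), THRSP (2.94) and ELOVL6 (1.76). Of 14 immediate early and heat shock genes 8 were in the table, also all higher in HC-L, with FOS at 18119 ± 15075 against 840 ± 424 (4.43), HSPH1 at 1.94, DNAJB1 at 2.74, EGR1 at 3.54, FOSB at 3.77 and MYC at 2.30. Since most genes of the table were higher in HC-L, these lists of 8 gave a Fisher exact p of 0.0603 each (adjusted 0.0603). Of the 10 positional genes, 3 were higher in HC-L (HOXC8 4.01, HOXC6 2.62, HOXC5) and 7 in HC-P (among them TBX1, HOXA7 -1.85, IRX5 -2.79 and HOXC11, which is listed at 0 in HC-L), with a Fisher exact p of 0.0141 (adjusted 0.0282).

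Fibre type genes were few in the table. Slow fibre CSRP3 (4.52) and ANKRD2 (2.04) and fast fibre TNNC2 (1.22) were higher in HC-L, and the CSRP3 values in HC-L were 1437, 2535 and 21935. MDH1 of the TCA cycle (-1.17) and the complex III gene UQCRFS1 (-1.02) were higher in HC-P, and the cytochrome oxidase subunit COX6A2 (1.22) in HC-L. The myogenic regulators MYF6 (1.53) and MSTN (1.91) were higher in HC-L. The lists glycolysis and glycogen, mitochondrial biogenesis and oxidative regulators, extracellular matrix and fibroblast, endothelial, immune, erythroid, nerve and Schwann, and exosome biogenesis and sorting had 0 genes in the table.

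**Figure D4:**
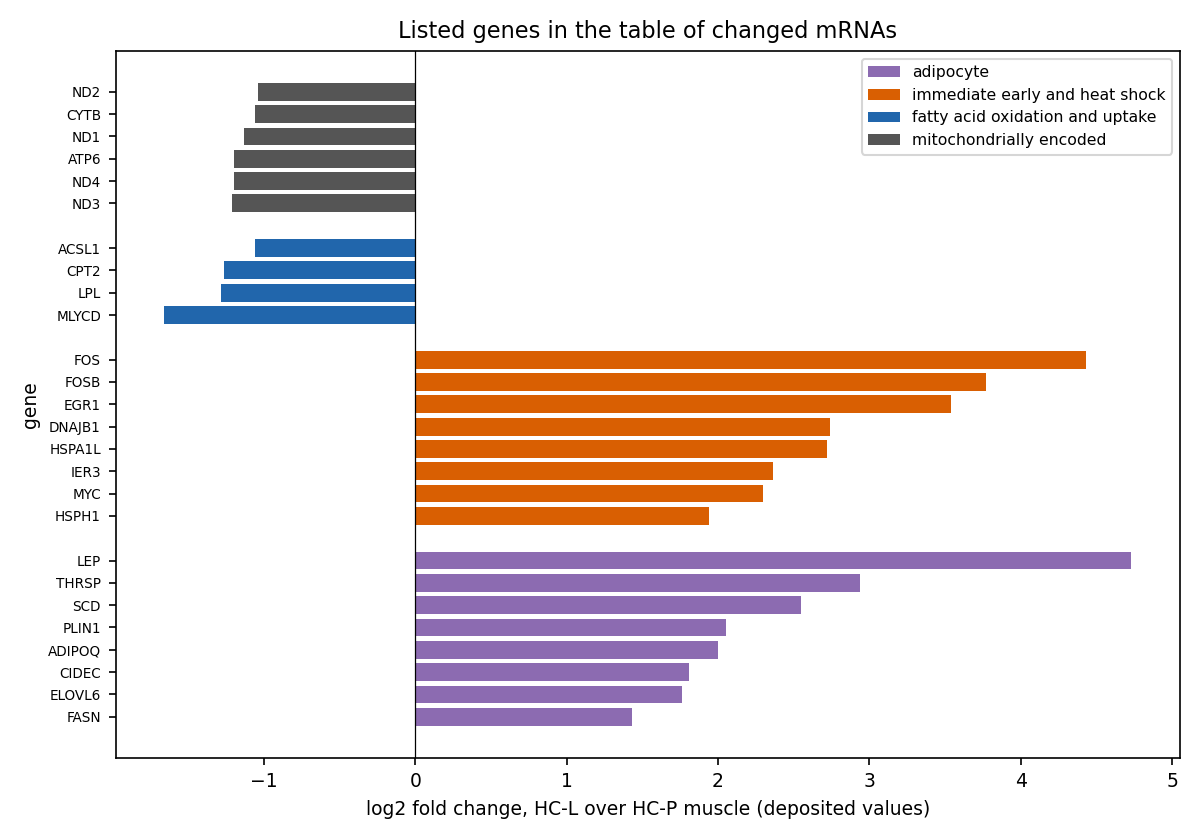
Log2 fold change of HC-L over HC-P muscle mRNA, from the deposited values, with a bar per gene for 3 lists and the mitochondrially encoded genes (n = 3 per group). All 8 adipocyte and all 8 immediate early and heat shock genes of the table lay above 0, and the 4 fatty acid genes and 6 mitochondrially encoded genes below 0.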

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

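All tests weighed in this part were chosen after the results they address had been seen, except the counts over other splits of the libraries.

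The exosome-tissue difference of miR-4331-3p differed between the muscles by -3.19 ± 0.88 on the log2 scale in the test of the difference itself, where it passed 0.05 before but not after adjustment (edgeR adjusted p = 0.712). Over 20 alternatives this value ran from -3.58 to -1.75 and its adjusted p from 0.123 to 1. Groups of 3 libraries were too small for the check on single libraries far from the rest.

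The surplus of miR-4331-3p in HC-P exosomes over HC-L exosomes was weighed first. Its reads did not grow with the exosome library total (slope -0.02 ± 0.27, and 0.21 within muscles), and the same number of background reads in every exosome library is argued against only because HC-P exosomes held 2.27 times the raw reads of HC-L exosomes (188 against 83, exact 95% interval 1.74 to 2.97). That interval covers counting error only and no spread between libraries. By library, HC-P exosomes held 84, 51 and 53 reads and HC-L exosomes 27, 30 and 26, and with 3 libraries per group the argument is weak. A number of background reads that differs between the preparations of the muscles stays open, as does a difference between the muscles. The size of the difference may rest in part on shallow libraries with a high miR-4331-3p share, since the log2 fold change went from -2.0 to -0.91 without the 3 shallowest exosome libraries, but this leaves HC-P replicate 1 alone against 2 HC-L libraries (edgeR adjusted p = 1), with a spread taken from the other groups. Whether reads of another RNA were counted as miR-4331-3p cannot be told apart from a variant in the 5p arm: in the exosome libraries numbered 2, where miR-4331-5p had 1 read each, miR-4331-3p kept 0.853 of the mean reads of the other 4.

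The 14 miRNAs called higher in exosomes of both muscles form the next pattern. Their reads hardly grew with the size of the exosome library: the median slope of log2 reads on log2 library total was 0.21, against 0.71 for the other 238 tested miRNAs (one-sided permutation p = 0.0319 over 720 orders of the 6 libraries). Those orders exchange libraries freely across muscles and replicate numbers. Same-numbered exosome libraries deviated together. The 14 were also selected for high values in these same libraries, a step that the orders do not repeat. This p may therefore not hold. Within muscles the median slopes were 0.25 against 0.66. Of the 14, 11 had a slope under 0.5, as did 33.2% of the other 238. A similar number of reads of the 14 entering every exosome library, from the preparation or from vesicles, would give such slopes. The highest slope of the 14 over the 6 libraries was that of novel_453, at 1.10 ± 0.36, and 0.82 ± 0.18 within muscles. Since novel_453 was singled out by this same slope, these values cannot decide against a similar number of reads in every library for it. Whether the larger tissue libraries play a part was not settled by thinning to 106040 reads: 100% of the 14 then had more reads in exosomes than in tissue in both muscles, but they had been selected for this, and the fit on thinned reads called 4 of 116 tested miRNAs higher in HC-L and 7 in HC-P, so enrichment in vesicles stays open.

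HC-P tissue replicate 1 was the last pattern weighed, because leaving it out raised the calls from 41 to 81 in HC-L and from 65 to 83 in HC-P. An exosome library under a tissue label is argued against by 0.504 CPM of miR-4331-3p, where exosome libraries held at least 40.0, and by its total of 3964875 reads. More red blood cells are argued against by 793 CPM of miR-451, inside the range of 582 to 2102 of the other 5 tissue libraries, although its miR-486 was high (14464 CPM against at most 1281). A lower share of miR-1 alone is argued against, because without miR-1 its spread against replicates 2 and 3 was 5.02 times the spread between these (2.05 against 0.41 on the log2 scale, 123 miRNAs). No biological explanation other than red blood cells was tested, and a different RNA or library preparation stays open.

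Other splits of the 6 libraries were too few for a share under 0.05 in the contrasts of 3 against 3. In HC-L exosomes against tissue 1 of 10 splits, the real one, gave 41 calls and the highest other gave 0; in HC-P 1 of 10 gave 65 and the highest other gave 0. Between the exosome groups and between the tissue groups the real split gave 0, as did all 10 splits. For the difference of the exosome-tissue differences the real value was 0, which all 100 of 100 splits reach by definition, so the splits say nothing on chance there; the highest other gave 2. In each contrast of 3 against 3, 4 splits part all 3 same-numbered pairs. They include the real one, and the others of these gave 0 calls.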

How the results depend on the processing

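Thinning, the fit without the 3 shallowest exosome libraries, lists with equal counts taken once and all settings of the arm comparison were chosen after the data had been seen. Of 1022 values under alternatives, 816 kept their direction and side of the threshold or, for counts, stayed within 1.5 times, 166 lost their call, 1 gained one, 39 moved and 0 reversed. The HC-L exosome-tissue count of 41 became 25 with DESeq2 size factors, 22 with library totals, 26 without the 3 most abundant miRNAs, 27 with at least 10 CPM, 68 with only the 2 groups, 7 after thinning and 17 without the 3 shallowest exosome libraries. The HC-P count of 65 became 36 with library totals, 40 with at least 10 CPM, 26 with only the 2 groups, 15 after thinning and 9 without the 3 shallowest libraries. Thinning left 116 miRNAs to test; the cause of the other shifts was not tested. The count between the exosome groups of 0 became 2 with DESeq2 and 1 without a filter, where novel_509 was called. The counts of 0 between the tissues and for the difference of differences became 28 and 5 without a filter. miR-4331-3p between the exosome groups was called by DESeq2 at -2.10. The 4 miRNA lists past the threshold became 0 with an estimated correlation. With adjusted p under 0.01 the 356 mRNAs higher in HC-L became 241 and the 166 higher in HC-P became 101.

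With a library left out, the HC-L count ran from 10 (without HC-L tissue replicate 2) to 81 (without HC-P tissue replicate 1) and the HC-P count from 31 (without HC-L tissue replicate 2 or HC-P exosome replicate 2) to 83 (without HC-P tissue replicate 1). The HC-L count moved by over 1.5 times without any one library except HC-P exosome replicate 1, and the HC-P count without any HC-L tissue or HC-P exosome library or HC-P tissue replicate 2 or 3. The 3 other counts stayed at 0 to 0. The lists past the threshold ran from 3 to 8 and the hairpins with a changed arm ratio from 10 to 12, against 11. With an mRNA library left out, 325 to 347 of the 356 genes higher in HC-L and all but 8 to 24 (at most 158) of the 166 higher in HC-P kept their direction and an absolute log2 ratio of group means of at least 1, among genes chosen for differing. miR-4331-3p ran from 5.81 to 6.34 in HC-L, from 8.86 to 9.44 in HC-P, from -2.32 to -1.78 between exosomes, from 0.83 to 1.26 between tissues and from -3.58 to -2.61 for the difference of differences. Of the named miRNAs, miR-10386 and miR-1285 in both muscles, novel_453 and miR-30e-5p in HC-L, and novel_295 and novel_509 in HC-P kept their call in every alternative run, while miR-208b in HC-L lost it in 16 of 22 and miR-19b in 15 of 21. Where a group was left with fewer libraries, the fit assumes that they vary like the others.

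The replicate block gave 41 calls in HC-L, 59 in HC-P, 0 in the other 3 contrasts and 4 lists, and miR-4331-3p at -1.91 between exosomes. Under the block miR-1468 in HC-L (adjusted p = 0.0534) and miR-1306-5p in HC-P (adjusted p = 0.0571) lost their call, and it changed no other call of a named miRNA. In HC-P same-numbered exosome and tissue libraries correlated weakly (0.11, 0.04 and 0.14), and that contrast was not tested alone for pairing. The mRNA calls are those of the authors, and no paired fit of them was run. Depth limits the exosome side: the floor of 3 reads used here is 28.3 CPM of the library total in the smallest library, and lower values there rest on 1 or 2 reads.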

Other observations

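The test on mitochondrially encoded genes and that on replicate numbers were chosen after the data had been seen, and that on genes related to miR-4331-3p before.

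All 6 mitochondrially encoded genes in the mRNA table were higher in HC-P muscle. These were ND1, ND2, ND3, ND4, CYTB and ATP6, with log2 fold changes of HC-L over HC-P from -1.21 to -1.04 (two-sided Fisher exact p = 0.000972 for their direction against the other genes of the table, which counts the 6 as independent although they are transcribed together). The others searched for by symbol, ND4L, ND5, ND6, ATP8, COX1, COX2 and COX3, were not found among the called genes, so their direction is not known. ATP6 was at 323639 ± 99242 normalised reads in HC-P against 141159 ± 39208 in HC-L (SD, n = 3), and ND4 at 206149 ± 67660 against 89616 ± 17054. The HC-L libraries were uneven: in 292 of the 522 genes (55.9%) HC-L library 3 was the one nearest to HC-P, against 148 and 82 for the other two.

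miR-4331-5p was nearly absent from every small RNA library numbered 2. It had 0 reads in replicate 2 of both tissues and 1 read in replicate 2 of both exosome groups, while the other tissue libraries held 49 and 51 reads in HC-L and 115 and 54 in HC-P, and the other exosome libraries 4 to 12. The hypothesis that equal numbers mark the same pig was tested on all 252 miRNAs. The mean correlation of deviations from group means over the 18 pairs of same-numbered libraries was 0.19, and the highest of the other 215 numberings gave 0.16 (one-sided exact permutation p = 0.00463, the smallest that 216 numberings can give). Equal numbers may therefore mark the same pig, although a shared day of handling would give the same.

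The mRNA table names miRNAs related to each gene, by a method not given in the sources used here. The hypothesis that genes related to miR-4331-3p are lower in HC-P, whose exosome libraries held more reads of it, was tested on direction: 34 of the 46 related genes (73.9%) and 322 of the 476 others (67.6%) were higher in HC-L (two-sided Fisher exact p = 0.413). This leaves the hypothesis open.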
